A study of Homo sapiens with 6 samples.

How the data were processed

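RNA of HaCaT cells, an immortalised human keratinocyte line, was measured on 6 one-colour Agilent expression arrays, 3 from cells given monosodium urate (MSU) crystals and 3 from cells left in medium. Per the labels' protocols, the experiment was done in triplicate, cells were kept without serum for 12 h, then given MSU at 1 mg/ml or medium for 12 h, and 150 ng of total RNA per sample was amplified and labelled with Cy3. Each sample was put in its group by its label, and the replicate number is the label's own. The labels do not say whether the triplicates were separate passages, so the p-values measure the spread between these cultures.

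The deposited scanner files hold the intensity of every spot on a linear scale as Agilent Feature Extraction wrote it, per the file headers. The version is 10.7.1.1 in the headers and 10.7.3.1 in the submitters' processing notes, and this difference was not resolved. The processed signal in these files was background-subtracted by the software and can lie at or under 0. The authors also deposited one table of log2 values for 24198 probes, all of them among the probes kept here. Compared with the scanner values, that table is on a log2 scale with each probe centred on its median over the 6 arrays, and each column correlated with the centred scanner values across probes at r of 0.9978 to 0.9995 (probes are not independent replicates). Its column medians are -0.0117, -0.00179 and -0.00877 for Control 1 to 3 and 0.00768, 0.0113 and -8.02e-05 for MSU 1 to 3. It was used only as an alternative. The files name the array design against the hg19 build. Genes were named through a table of the GRCh38.p14 RefSeq annotation by accession without version, so no coordinates are given.

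Each array holds 62976 spots, 61657 of them not controls, for 50683 distinct probes. A symbol was found for 28174 probes and none for 22509, which kept the name in the files. Signals were scaled so that every array had the same 75th percentile, set to a floor of 5 scaled signal units and taken to log2. The floor was chosen after seeing that 14.1% to 16.5% of spots per array lay at or under 0. Spots flagged as outliers were left out, which removed 26 probes, and the spots of a probe were averaged. Probes well above background, by the software's flag, on every array of at least 1 group were kept, which left 28067. The brightest kept probe stood for each gene, which gave 22443 features, 15110 with a symbol and 7333 without. Of these, 21296 were well above background on all 6 arrays. Among the named genes, 19 had several kept probes, and none of them had a probe of opposite sign.

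Where a gene was not well above background on any array of a group, its change is given as a bound: the mean log2 value of the bright group against the mean, over the dim group's arrays, of the lowest signal well above background or the probe's own signal, whichever was higher. No other fold is given for such a gene, apart from its change under normexp where stated, an alternative described below.

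Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Adjusted p-values below are from this fit unless another test is named. A list of 36 gene groups with 755 genes was fixed before the data were examined, as were the tests, most of the alternatives and the rule for naming genes. Of these lists, 34 had at least 5 genes tested. Lists were tested with limma's camera at a preset correlation of 0.01, with camera's estimated correlation and with fry. Counts of genes adjusted over a list alone were not among the tests fixed beforehand. They are not corrected across the lists. The genes named were the 14 largest rises and falls past the threshold with groups that do not overlap and signal well above background on all 6 arrays, the 5 largest bounds each way, up to 4 called members per list (or the 2 with the smallest p), and 8 inflammation genes. The same rule was applied to the fit with the slide as a block, and this was added after the data were seen.

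The arrays lay on 3 slides, per the file headers. Each slide held the Control and the MSU array of one replicate number, with all Control arrays at position 1 and all MSU arrays at position 3, so position on the slide and treatment coincide. Slide, scan and replicate number were the same division of the arrays. To check whether the numbers pair the samples, each array's deviations from its group mean were correlated across genes. Arrays with the same number correlated at 0.517, 0.487 and 0.531, each over the threshold of 0.1, and the 6 pairs with different numbers correlated at -0.419 to -0.124. The numbers therefore pair the samples, and values from the fit with the slide as a block are given beside the unblocked ones. That fit has 2 residual degrees of freedom, against 4 without the block.

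The 75th percentile of the processed signal was 752.8, 740.7 and 712.8 on Control arrays 1 to 3 and 809.5, 639.4 and 769.1 on MSU arrays 1 to 3. Between 56.1% and 60.4% of spots were well above background. The spike-in slopes were 1.011 to 1.034. The number of arrays, 3 per group, limits the precision.

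Both fits were tested on simulated data with 22443 genes, with the changed genes picked at random. Each gene's spread was taken from these arrays and shrunk toward a common value. Without the block, 66% of genes changed by a log2 fold of 1 and 90% of those changed by 2 were recovered, with no false calls. With the block the shares were 98% and 99%, and 8.37% of the calls were false. These shares hold for the simulated genes and need not hold for the real ones. In the data, 364 features differed by a log2 of 1 or more, which may include noise. Of these, 10 were called without the block and 122 with it. In the same simulation camera called the 1 changed list and 0 of 30 unchanged lists. The simulated genes were drawn independently, so this does not test camera where the genes of a list vary together. Some real lists did so, with an estimated correlation of 0.5476 for ribosome biogenesis.

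The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization or the median in place of the 75th percentile, no filter or a stricter filter on dim probes, every probe or the mean of a gene's probes, eBayes with trend and robust, the authors' values, the replicate block, and each array left out in turn. The files used hold no mean signal, so normexp was run on the median signal and the median background. Floors of 1 and 16, and the alternatives applied to the blocked fit, were added after the data were seen. Groups of 3 are too small for a test of outlying samples, so none was made.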

Results

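Gene expression was measured in HaCaT keratinocytes after 12 h with MSU crystals, the crystals that form in gout, at 1 mg/ml, and in cells kept in medium for the same time. There were 3 arrays per group, in pairs of 1 Control and 1 MSU array on each of 3 slides. Per array, 34604 to 37227 of the 61657 spots were well above background. Saturation was found on 1 array alone, MSU 3, at 2 spots. The design implies a single comparison, which asks which transcripts differ between crystal-treated and untreated keratinocytes. Differences are MSU minus Control on the log2 scale of the scaled signal, with the standard error (SE) of the limma fit. For genes called with the slide as a block alone, and where a paired p is the only one given, the SE is that of the fit with the block.

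Several inflammatory genes were higher with MSU. CXCL8, the neutrophil-attracting chemokine, went from 6.12 ± 0.18 to 9.96 ± 0.55 (mean ± SD of log2 signal, n = 3), a difference of 3.84 ± 0.28 (SE) or 14.3-fold (limma adjusted p = 0.0228). TNFAIP3, which encodes the NF-kB inhibitor A20, rose by 2.52 ± 0.12 (adjusted p = 0.00489). The chemokine CXCL1 rose by 2.14 ± 0.16, and the calcium-binding alarmins S100A9 and S100A12 rose by 1.98 ± 0.14 and 1.92 ± 0.14 (each adjusted p = 0.0228). OLR1, a scavenger receptor for oxidised lipoprotein, rose by 1.55 ± 0.12 (adjusted p = 0.027), and the immediate early gene IER3 by 1.19 ± 0.09 (adjusted p = 0.0228). IL17C, an epithelial cytokine, was not well above background on any Control array and was at least 6.01-fold higher with MSU on the background-subtracted signal (adjusted p = 0.00489). That p was computed on the floored values and not on the bound. The Control values of IL17C, 2.32, 2.32 and 2.41, lay at or near the floor, which narrows their spread. After normexp, which adds an offset of 50 signal units, the IL17C change was 1.34. Over the settings the CXCL8 difference ran from 3.03 to 4.13. Within the slides it was 4.18, 4.07 and 3.27, and the TNFAIP3 difference 2.60, 2.58 and 2.38.

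In all, 10 of 22443 features changed at an adjusted p under 0.05 in limma, 10 higher and 0 lower, and all 10 by at least 2-fold. All 10 had the same sign on the 3 slides. The other 2 were transcripts without a symbol, ENST00000517927, at least 23.9-fold higher, and ENST00000412075, at least 2.68-fold higher, neither of them well above background in Control. With normexp they differed by 2.95 and 0.53, less than these bounds. All Control values of ENST00000517927 lay at the floor, with an SD of 0, so its call also rests partly on the floor. At an unadjusted p under 0.05 there were 1357 features higher and 1397 lower. The groups did not overlap for 20.5% of features, where chance gives 10% if the arrays are interchangeable, which their pairing by slide goes against. With the slide as a block, the paired fit called 206 features, 136 higher and 70 lower, with 122 changed at least 2-fold. These included the 10 above, and all 206 had the same sign on the 3 slides. A gene with differing signs would hardly pass either fit, so this agreement largely follows from the calls. Over all features, 49.7% had the same sign on the 3 slides, where chance gives 25%. The split of higher and lower calls in the paired fit differed between settings: quantile normalization gave 99 and 26, and the authors' values, which cover fewer probes, 368 and 326. No filter on dim probes left 0 paired calls, and eBayes with trend and robust gave 1345. The unblocked count of 10 fell to 0 without Control 1, Control 2 or MSU 2, to 1 without Control 3 and to 4 without MSU 1. The paired count of 206 fell to 22, 12 and 37 without slides 1, 2 and 3.

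**Figure D1:**
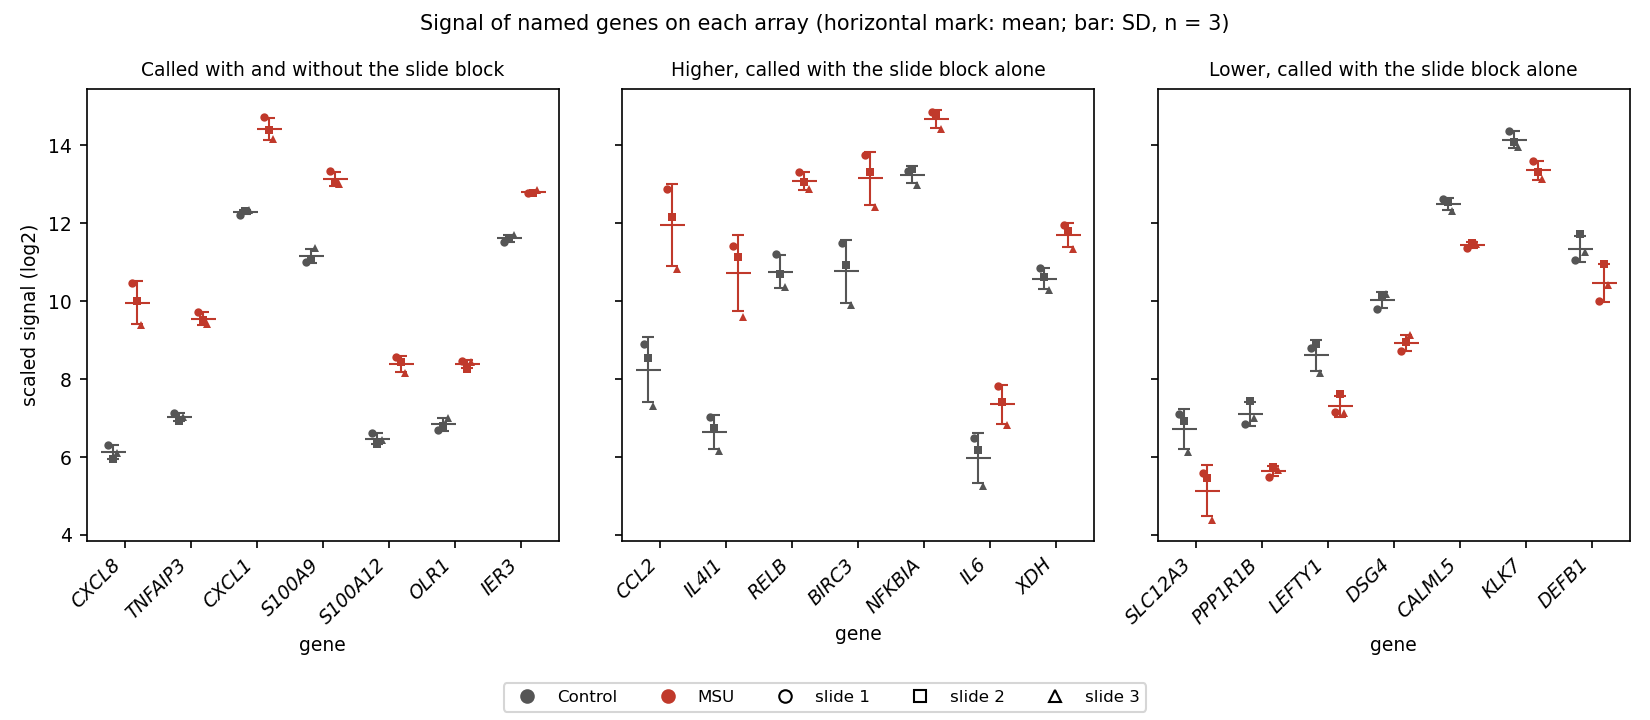
Log2 scaled signal (vertical axis) of 21 named genes on each array, with Control in grey, MSU in red, a marker shape per slide, the mean as a horizontal mark and the SD as a bar (n = 3). The 3 MSU points lie above the 3 Control points for all 7 genes of the left panel, as the rule that named these genes required. They also do so for IL6 and BIRC3 in the middle panel. The levels of IL6 and BIRC3 differ between slides in both groups, and the within-slide gap is 1.24 to 1.56 and 2.26 to 2.51.

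Of 26 inflammatory cytokines and chemokines tested, 2 rose without the block and 24 did not pass, and 12 rose with the slide as a block. Adjusted over the list alone, 16 rose without the block and 19 with it. The monocyte-attracting chemokine CCL2 was 3.72 ± 0.12 higher (SE with the block, paired adjusted p = 0.00682, 0.166 without the block), and by at least 3.52 on each slide. CXCL3 was higher on all 3 slides (paired adjusted p = 0.00862, 0.17 without), but was well above background on 2 of 3 Control arrays, and the size of its change depended on the setting, from 2.44 to 5.01. CCL20 and IL36G were not well above background in Control and were at least 13.4-fold and 11.2-fold higher (paired adjusted p = 0.0221 and 0.00682, each 0.0811 without). With normexp the changes of CCL20 and IL36G were 1.94 and 1.83, less than these bounds. IL6 was 1.38 ± 0.10 higher (paired adjusted p = 0.0221, 0.30 without), and TNF was also higher on all 3 slides (paired adjusted p = 0.00775, 0.215 without). TNF was well above background on 1 of 3 Control arrays, and its change ran from 0.76 to 2.16 over the settings. The median change of the list was 1.38, or 1.28 with genes not above background at their bound, and 1.79, 1.22 and 1.29 within slides (camera adjusted p = 3.02e-18). That call was lost with an estimated correlation (adjusted p = 0.0898).

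IL1A was not well above background in Control and at least 1.76-fold higher with MSU (paired adjusted p = 0.0308, 0.0512 without the block). With normexp the IL1A change was 0.42, less than this bound. IL1B, the cytokine that crystals are known to release through the inflammasome, differed by 1.39 ± 0.22 and did not pass either fit (adjusted p = 0.146, paired 0.0694), although it was higher on all 3 slides. PTGS2, the inducible prostaglandin synthase, differed by 0.80 ± 0.65 and did not pass (adjusted p = 0.657, paired 0.059). NLRP3, the inflammasome sensor, had no probe that met the background filter and was not tested. Of 17 inflammasome and pyroptosis genes tested, 0 passed without the block (limma, with 3 past it when adjusted over the list alone) and 1, IL1A, with it. The list was not called by camera (median 0.01, camera adjusted p = 0.156). The mixed fry test, which asks for change in either direction, did call it (adjusted p = 0.000298). CASP1 differed by 0.01 ± 0.07 (SE with the block, paired adjusted p = 0.935) and PYCARD by -0.01 ± 0.09 (paired adjusted p = 0.94).

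Some genes that NF-kB induces, among them its own inhibitors, were higher. TNFAIP3 alone of 19 tested passed without the block, 9 rose with it, and 13 and 15 rose adjusted over the list alone. RELB, a subunit of NF-kB, was 2.33 ± 0.11 higher (paired adjusted p = 0.0104, 0.0778 without the block), the apoptosis inhibitor BIRC3 2.39 ± 0.09 (0.00682 and 0.214) and the NF-kB inhibitor NFKBIA 1.44 ± 0.08 (0.0151 and 0.0811). The list's median change was 0.67, and 0.83, 0.63 and 0.66 within slides (camera adjusted p = 9.62e-17, lost with an estimated correlation, adjusted p = 0.249).

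Among 17 antimicrobial peptides and S100 proteins, S100A9 and S100A12 rose without the block, and 7 rose and 1 fell with it. Adjusted over the list alone, 10 rose and 1 fell without the block. S100A8, the partner of S100A9, was 2.33 ± 0.21 higher (paired adjusted p = 0.0365, 0.143 without the block), the elastase inhibitor PI3 2.29 ± 0.24 higher (0.0468 and 0.127) and the acute phase protein SAA1 0.85 ± 0.08 higher (0.0396 and 0.409). The constitutive defensin DEFB1 was lower by -0.89 ± 0.10 (0.0479 and 0.331). The median change was 1.09, and 0.98, 1.07 and 0.65 within slides (camera adjusted p = 2.78e-08, lost with an estimated correlation, adjusted p = 0.0898). LCN2, the siderophore-binding lipocalin, was 1.23 ± 0.13 higher (paired adjusted p = 0.0468, 0.326 without the block).

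Of 29 EGFR ligands and ERK-responsive genes, IER3 rose without the block and 4 rose with it, and 13 and 16 rose adjusted over the list alone. The phosphatase DUSP6 was 1.29 ± 0.08 higher (paired adjusted p = 0.0197, 0.0811 without the block), the EGFR ligand HBEGF 1.32 ± 0.11 (0.0318 and 0.0811) and JUN 0.77 ± 0.08 (0.0479 and 0.369). The list had a median of 0.76, and 0.59, 0.62 and 0.71 within slides. It was the one list also called with an estimated correlation (camera adjusted p = 2.02e-13 preset and 0.033 estimated), and that call was lost with the slide as a block (adjusted p = 0.267 estimated). Of 20 matrix proteases and inhibitors, 0 passed without the block in limma and 5 rose with it. MMP9 was 1.82 ± 0.19 higher (paired adjusted p = 0.0468), MMP7 1.15 ± 0.09 (0.0242), the plasminogen activator PLAT 1.59 ± 0.16 (0.0453) and the urokinase receptor PLAUR 0.85 ± 0.10 (0.0498). Adjusted over the list alone, 5 rose and 1 fell without the block and 11 rose and 2 fell with it. The median was 0.52 (camera adjusted p = 0.00129, lost with an estimated correlation, adjusted p = 0.2605).

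**Figure D2:**
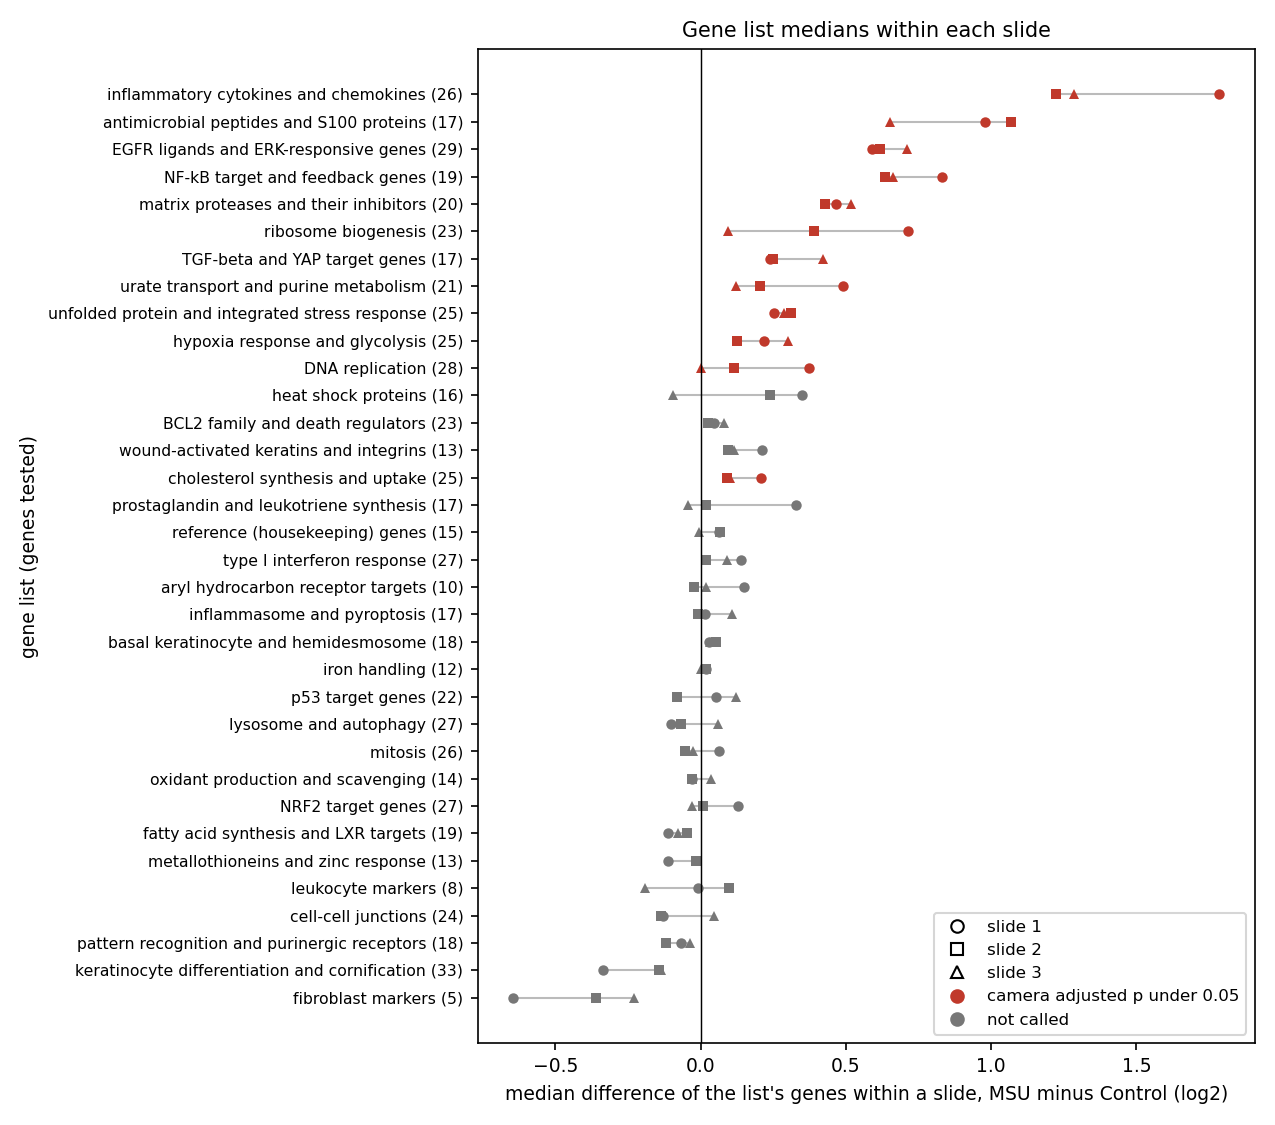
Median within-slide difference, MSU minus Control in log2 (horizontal axis), of each of 34 gene lists (vertical axis, with the number of genes tested), a marker shape per slide and lists called by camera in red. The inflammatory list lies at 1.22 to 1.79 on the 3 slides, while ribosome biogenesis ranges from 0.10 to 0.72 and DNA replication from 0.00 to 0.37.

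The remaining 7 called lists moved less. No gene of ribosome biogenesis (23 tested), DNA replication (28), cholesterol synthesis and uptake (25), unfolded protein and integrated stress response (25) or hypoxia response and glycolysis (25) passed either fit in limma. Adjusted over the list alone without the block, 4 cholesterol genes and 1 stress response gene rose, and none of the other 3 lists. With the block, also adjusted over the list alone, 4 cholesterol and 11 hypoxia genes rose, 9 stress response genes rose and 1 fell, and none of the ribosome biogenesis or DNA replication lists passed. RRS1, a ribosome assembly factor, differed by 0.61 ± 0.15 (adjusted p = 0.261). The stress-induced transcription factor ATF5 differed by 0.97 ± 0.19 (0.185) and VEGFA, the vascular growth factor, by 0.68 ± 0.21 (0.326). Their medians were 0.38 (camera adjusted p = 1.15e-10, with an estimated correlation adjusted p = 0.34), 0.18 (3.07e-05 and 0.632), 0.09 (0.000444 and 0.34), 0.25 (0.00201 and 0.67) and 0.20 (0.0138 and 0.92) in the order listed. The hypoxia call was lost with quantile normalization, with the authors' values, without Control 1 and without MSU 3, and the stress response call without MSU 3.

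Among 21 urate transport and purine metabolism genes, XDH, which encodes the oxidase that makes urate, rose by 1.11 ± 0.08 in the paired fit (adjusted p = 0.0221, 0.178 without the block), with 1.11, 1.18 and 1.05 on the slides. The others did not pass. PNP, the enzyme of purine salvage, differed by 0.53 ± 0.10 (adjusted p = 0.196, paired 0.0874). Adjusted over the list alone, 2 rose without the block, and 4 rose and 1 fell with it. The list's median was 0.27 (camera adjusted p = 1.49e-06, lost with an estimated correlation, adjusted p = 0.34). Of 17 TGF-beta and YAP target genes, INHBA, an activin subunit, rose with the block by 1.30 ± 0.09 (paired adjusted p = 0.0221, 0.0811 without), and 2 rose without the block and 9 with it adjusted over the list alone. That list's median was 0.30 (camera adjusted p = 0.000567, lost with an estimated correlation, adjusted p = 0.265).

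In all, camera called 12 of 34 lists, 12 up and 0 down, and 12 with the slide as a block. Estimated correlation left 1 list without the block and 0 with it. The directional fry test called 4 lists, the inflammatory (adjusted p = 0.00357), EGFR (0.00177), antimicrobial (0.00357) and NF-kB (0.0154) lists. The mixed fry test, which asks for change in either direction, called 17. With the slide as a block the directional fry test called the same 4 lists. It then also called the basal keratinocyte (fry adjusted p = 0.0184) and BCL2 family (0.02855) lists, which camera did not. Divisions of the 6 arrays that kept the pairs of 2 slides whole gave 9 to 17 lists at the preset correlation.

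Keratinocyte differentiation genes went both ways. Of 33 tested, 0 passed without the block in limma, and 2 rose and 2 fell with it. Adjusted over the list alone, 7 rose and 7 fell without the block, and 9 rose and 14 fell with it. The cornified envelope precursors SPRR1A and SPRR3 were 2.27 ± 0.16 and 0.92 ± 0.09 higher (paired adjusted p = 0.0234 and 0.0448, 0.17 and 0.204 without the block). A second SPRR1A probe, also well above background on all 6 arrays, differed by 0.87, so the size of that change is uncertain. The calcium-binding protein CALML5 was lower by -1.05 ± 0.11 (0.0457 and 0.0811) and the desquamation protease KLK7 by -0.79 ± 0.07 (0.0404 and 0.215). The structural proteins IVL and LORICRIN differed by -0.72 ± 0.12 and -0.74 ± 0.15 and did not pass (paired adjusted p = 0.0848 and 0.0976). The list was not called (camera adjusted p = 0.475), and its median of -0.26 and mean of 0.06 differ in sign. It was among the 17 lists called by the mixed fry test for change in either direction (adjusted p = 0.00071). Outside the list, SPRR2A and SPRR2E were 3.53 ± 0.39 and 3.61 ± 0.40 higher (each paired adjusted p = 0.0489), but the SPRR2 genes are close copies and their probes may share signal, so which members changed is uncertain.

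**Figure D3:**
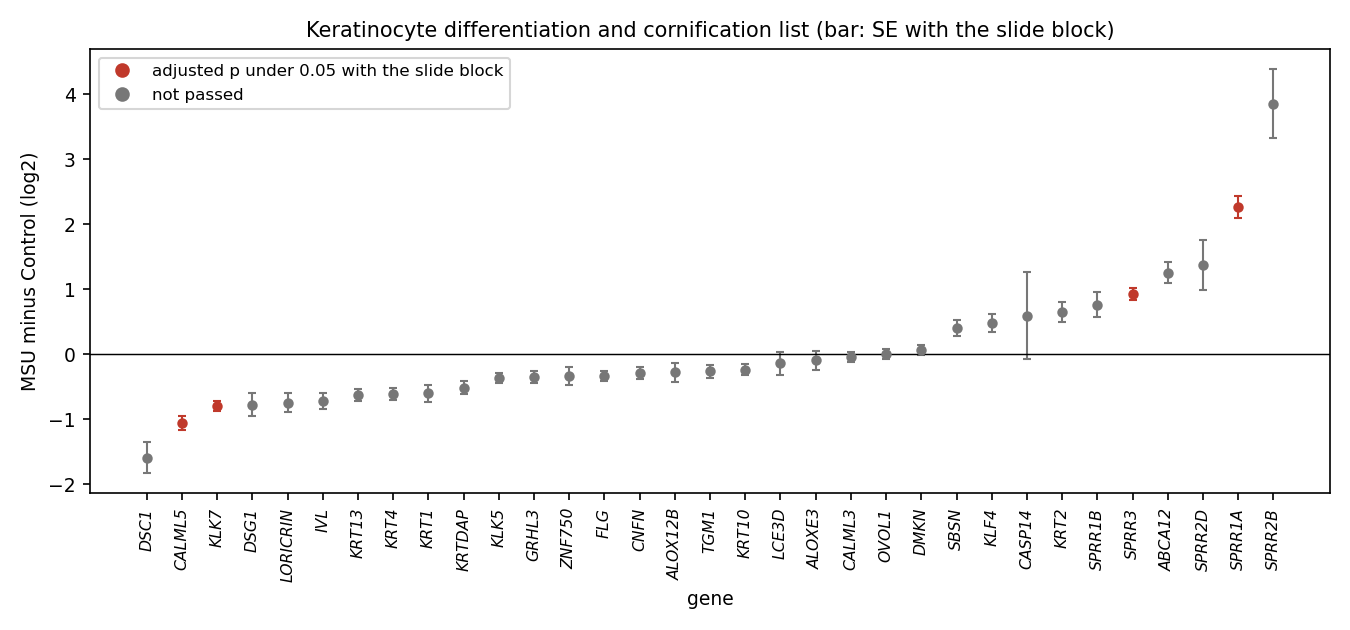
Difference of MSU minus Control in log2 (vertical axis) for the 33 keratinocyte differentiation genes tested (horizontal axis), with the SE of the fit with the slide as a block as the bar and genes past an adjusted p of 0.05 in that fit in red. SPRR1A at 2.27 (a second probe, not shown, stood at 0.87) and SPRR3 at 0.92 passed above 0, and CALML5 at -1.05 and KLK7 at -0.79 passed below it.

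Other large rises in the paired fit were those of IL4I1, a secreted amino acid oxidase, by 4.08 ± 0.22 (adjusted p = 0.0151, 0.0811 without the block), the ubiquitin-like protein UBD by 3.33 ± 0.13 (0.00682 and 0.321) and GFPT2, an enzyme of hexosamine synthesis, by 3.02 ± 0.10 (0.00682 and 0.127). UBD had a Control SD of 1.64, yet its differences on the slides were 3.03, 3.55 and 3.43. The amino acid transporter SLC6A14 was 2.44 ± 0.08 higher (0.00682 and 0.302). Over the settings IL4I1 ran from 3.48 to 4.63, UBD from 2.45 to 4.17, GFPT2 from 2.12 to 3.40 and SLC6A14 from 1.74 to 3.00. VNN1, a pantetheinase, and KYNU, the kynureninase of tryptophan breakdown, were not well above background in Control and at least 5.70-fold and 4.38-fold higher (paired adjusted p = 0.0479 for VNN1 and 0.0217 for KYNU, 0.161 and 0.0811 without the block). With normexp their changes were 1.11 and 0.92. TLR2, the receptor for bacterial lipoproteins, was 1.26 ± 0.11 higher (0.0365 and 0.0811), and the BH3-only protein BIK 0.94 ± 0.09 higher (0.0404 and 0.0811). ISG20 was 0.72 ± 0.08 higher (0.0489 and 0.553).

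The largest falls in the paired fit were smaller than the largest rises. SLC12A3, the thiazide-sensitive sodium chloride cotransporter, was lower by -1.58 ± 0.09 (adjusted p = 0.0196, 0.261 without the block), PPP1R1B, a phosphatase inhibitor, by -1.46 ± 0.11 (0.0242 and 0.0811) and LEFTY1, a Nodal antagonist, by -1.31 ± 0.14 (0.0468 and 0.172). Over the settings SLC12A3 ran from -1.87 to -0.69 and PPP1R1B from -1.59 to -0.74, with the smallest falls under normexp. The desmosomal cadherin DSG4 was lower by -1.10 ± 0.08 (0.0234 and 0.127), and INHBB, another activin subunit, by -1.08 ± 0.08 (0.0223 and 0.17). The phospholipase PLA2G2A was lower by -0.95 ± 0.09 (0.0383 and 0.367), and the WNT antagonist SOST by -0.97 ± 0.08 (0.0317 and 0.237). ANXA9, TMT1B, PLCD4, FAM171B, UMODL1 and MAL also fell, by log2 differences from -1.12 for ANXA9 to -0.95 for MAL, with paired adjusted p of 0.0308 for TMT1B and UMODL1 and up to 0.0498 for ANXA9 and MAL. Over the settings the smallest falls were -0.40 for UMODL1, -0.50 for TMT1B, -0.51 for PLCD4, -0.65 for FAM171B, -0.76 for MAL and -0.88 for ANXA9.

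The other 21 tested lists beside differentiation were not called at the preset correlation. They included NRF2 targets (27 tested, median -0.03, camera adjusted p = 0.75), heat shock proteins (16, 0.15, 0.112), p53 targets (22, 0.00, 0.149), type I interferon response (27, 0.06, 0.475), mitosis (26, -0.02, 0.772), oxidant production (14, -0.02, 0.772), lysosome and autophagy (27, -0.01, 0.963), metallothioneins (13, -0.06, 0.235), cell-cell junctions (24, -0.08, 0.772) and wound-activated keratins (13, 0.09, 0.0655). Some of the 21 were called by the mixed fry test for change in either direction. These were the p53 (adjusted p = 0.000298), oxidant (0.000298), BCL2 family (0.00071) and pattern recognition (0.00103) lists. The aryl hydrocarbon receptor (0.0114), heat shock (0.0261), fatty acid (0.0272) and inflammasome lists were called as well. Adjusted over the list alone, 4 p53 targets rose without the block, and 3 heat shock genes rose and 3 fell with it. The NRF2, p53, leukocyte, prostaglandin, aryl hydrocarbon receptor, lysosome and pattern recognition lists had a median that differed in sign from the mean or from the camera direction. Among markers of other cell types, the 8 leukocyte genes tested had a median of -0.08, with PTPRC at -0.16 ± 0.10, ITGAM at 1.03 ± 0.15 and CD68 at 0.23 ± 0.08, none of which passed (SE with the block, paired adjusted p = 0.398, 0.0649 and 0.204). Adjusted over the list alone, 1 leukocyte gene, ITGAM, rose with and without the block. The 5 fibroblast genes had a median of -0.41, and COL1A1 differed by -0.41 ± 0.11 (paired adjusted p = 0.142). The melanocyte and endothelial lists had fewer than 5 genes tested, with PMEL at -0.40 ± 0.08 (0.0945) and VWF at -1.25 ± 0.20 (0.0758). A second VWF probe well above background on all 6 arrays stood at -0.19. The reference genes had a median of 0.07 (camera adjusted p = 0.0672), against -0.03 for all features.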

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

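The floors of 1 and 16, the alternatives to the paired fit and the summaries of single genes were chosen after the data were seen. Of 2117 values of the 119 named genes under the alternatives, 1970 kept their direction and their side of the threshold, 61 were no longer past it, 85 came to pass it and 1 changed sign, MLANA, which stood at -0.0521 without Control replicate 2 and at 0.3613 without Control replicate 3. Only the 10 calls could stop passing, so all 61 of those values were theirs. Most of the 1970 values belong to genes that did not pass the unblocked fit. TNFAIP3 passed in 13 of 18 alternatives, CXCL8 in 12 of 18, IER3 in 11 of 18 and ENST00000517927 in 9 of 16. Over their alternatives the highest adjusted p of the 10 calls ran from 0.0732 for TNFAIP3 to 0.232 for IER3 and OLR1. With the replicate block, the paired values were 206 features changed, 136 higher, 70 lower and 122 at least 2-fold, and the list count stayed at 12. Of the 52 named genes called with the block and not without it, 37 were called under no setting without the block. The adjusted p of all 52 ran from 0.0254 to 0.81 over the settings without the block. Without the block, normexp with quantile normalization gave 34 changed, 32 higher, 2 lower and 29 at least 2-fold, 9 of them among the 10. Trend and robust gave 42, 41, 1 and 35. No filter on dim probes gave 1 changed, 1 higher and 1 at least 2-fold. Quantile and median scaling gave 1 lower gene each. Leaving out 1 array gave 0 to 13 changed, 0 to 12 higher, 0 to 1 lower and 0 to 13 at least 2-fold, with fewer arrays in each fit. The other settings gave 7 to 15 changed. An estimated correlation gave 1 list and fry 4, and the remaining settings 11 to 17.

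In the paired fit (replicate block), normexp with quantile normalization gave 748 changed, 433 higher and 315 lower, trend and robust 1345, 702 and 643, and the authors' values 694, 368 and 326. Quantile normalization gave 125 changed and 26 lower, with 122 of the 125 among the 206. No filter on dim probes gave 0, 0 and 0. The stricter filter gave 237 and the floors of 1 and 16 gave 168 and 201. Leaving out 1 slide gave 12 to 37 changed, 12 to 33 higher and 0 to 4 lower, with 1 residual degree of freedom. Apart from the smaller number of arrays, the cause of these differences was not tested. Signal over background limits the dim genes: 25 of the features tested were not well above background on any Control array and 71 on any MSU array. These have bounds only, apart from the changes stated under normexp.

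The 6 arrays make 10 divisions into equal groups, too few for a share under 0.05. The real division gave 10 features changed, 10 higher and 10 at least 2-fold, as did 1 of 10 divisions, and the highest other gave 0. For the 0 features lower, all 10 divisions gave as many. For the paired fit, the 4 divisions that part all 3 slide pairs are also too few, with 206 in the real one and at most 0 in the others, while divisions that leave 2 pairs whole gave 0 to 12. For the lists, 5 of 10 divisions gave 12 or more, with 17 as the highest other. The 4 that did so beside the real one all keep the pairs of 2 slides whole and so follow the slides. Among the 4 divisions that part all pairs, the highest other was 11.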

Other observations

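The test of leukocyte RNA was chosen after its result had been seen, and so were the genes of the next paragraph.

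Genes of antigen presentation by MHC class II were among those that rose in the paired fit. CIITA, the transactivator of the class II genes, was 0.79 ± 0.09 (SE) higher with limma (adjusted p = 0.0489, 0.301 without the block), HLA-DMB 0.91 ± 0.09 (0.0404 and 0.351) and HLA-DQA2 0.83 ± 0.08 (0.0453 and 0.599), each on 3 of 3 slides. The probes of HLA-DQA2 and HLA-DQA1 may share signal, so which of them changed is uncertain. LTB and TNFSF14, ligands of the TNF family, rose as well. LTB was not well above background in Control and at least 3.44-fold higher (paired adjusted p = 0.0365, 0.171 without the block), and TNFSF14 was 1.96 ± 0.08 higher (0.00775 and 0.365). The 2 chains of the bile acid and steroid transporter fell together in the paired fit, SLC51A (paired adjusted p = 0.0404, well above background on 1 of 3 MSU arrays, so its size is uncertain) and SLC51B by -0.91 ± 0.08 (0.0318). Among enzymes of tryptophan breakdown beside KYNU, IDO1 differed by 0.51 ± 0.08 and did not pass (paired adjusted p = 0.0781), and KMO by 0.05 ± 0.07 (0.702).

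The levels of some genes that rose in the paired fit differed between slides in both groups while the difference within slides varied less. UBD and SLC6A14 were called with the block and not without it. That choice favours this pattern, so it is a description and not a test. For UBD the SD of log2 signal was 1.64 among Control and 1.49 among MSU arrays, and the within-slide differences ran from 3.03 to 3.55. For SLC6A14 the SDs were 1.04 and 1.03, and the differences 2.41 to 2.50. The slides' differences correlated across all features at r of 0.56, 0.423 and 0.41 (features are not independent replicates).

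One hypothesis is that the class II genes rose as a group. It was tested on the 14 members not used to propose it, among them RFX5, RFXAP and RFXANK, which regulate the class II genes. HLA-DQA1, at 0.70, was 1 of the 14, and its probe may share signal with that of HLA-DQA2, at 0.83, which was used to propose it. The 14 are therefore not fully independent of the genes that proposed the group. None of the 14 had passed the paired fit. Their median change was 0.305 with 12 of 14 above 0, and camera at the preset correlation gave p = 0.0554, or 0.494 with an estimated correlation. With the slide as a block, a test added after the others were seen, the paired values were 5.57e-05 and 0.124. The call depends on the block and on the correlation between the genes, so the hypothesis stays open. A second hypothesis, that ligands of the TNF family rose as a group, was tested on 8 other members. None of these had passed the paired fit either. Their median was -0.0544 with 3 of 8 above 0. CD70 stood at 0.70 ± 0.09 and TNFSF10 at -0.72 ± 0.12, neither past the threshold (paired adjusted p = 0.059 and 0.0811). Camera from limma gave no sign of a rise of these ligands (p = 0.895, 0.898 with an estimated correlation and 0.997 with the slide as a block). The outcome set beforehand for no rise as a group was a low median with a camera p over the threshold. These values met it and argue against a rise of these 8 members as a group. A stricter rule that adds the members' SD to the median left it undecided, as they went both ways. A rise of single ligands may still be all there is.

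The rise of inflammatory, NF-kB and S100 genes coincides with the arrays' position on the slide. The 7 spike-in controls well above background differed between positions by at most 0.0947 (log2) as the mean over the slides, and by up to 0.317 on a single slide, and the smallest of the 10 called changes was 1.19, which argues against hybridisation or scanning at a position as the source. RNA of leukocytes in the treated wells was assumed to raise their markers by about the change of the inflammatory list, 1.38. The 8 leukocyte markers tested had a median of -0.081 with an SD of 0.458, with PTPRC at -0.16, CD68 at 0.23, TYROBP at 0.37 and FCER1G at -0.28. This argues against a shared rise of that size. ITGAM alone stood near that size, at 1.03 and higher on all 3 slides. It did not pass when adjusted over all features. Adjusted over the 8 markers alone, ITGAM rose with and without the block. HaCaT is a cell line with no sort or gate, and keratinocytes may express some of these markers, such as CD68, themselves. A marker with signal in Control, such as CD68 or ITGAM, would move less, so the test cannot exclude a smaller share of leukocyte RNA. A response of the keratinocytes to the crystals stays open as a hypothesis, as does one to any contaminant of the crystals, which no sample here tests.

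The ribosome biogenesis list differed by 0.72, 0.39 and 0.10 on slides 1, 2 and 3. A bias that depends on brightness could give such a shift on slide 1. The list's median of 0.715 on slide 1 was compared with the medians of 10000 random lists of the same size and brightness. With a share of 0.05 of them left out, equally from each side, these ran from -0.0674 to 0.189. Genes of ribosome biogenesis varied together (estimated correlation 0.5476), which genes drawn at random need not do. The random lists therefore show the shift that brightness alone would give, and not the spread between cultures. On slide 2 the list, at 0.389, lay above all such lists, and on slide 3 it stood at the 93.9 percentile. The scaling is another candidate explanation, but quantile normalization left the slide 1 median at 0.657. Neither accounts for the shift on slide 1. On that slide the 7 spike-ins were lower on the MSU array by 0.20 to 0.32 after scaling, and on the other slides they differed by -0.02 to 0.16. Of the growth lists on slide 1, DNA replication had a median of 0.372, above all 10000 random lists matched to it, and mitosis one of 0.0644, at the 26.7 percentile of its own. Genes of DNA replication and of mitosis also varied together (estimated correlation 0.4723 and 0.6052), so these ranks are no test of a change between cultures. The difference between these lists was not tested, and what differed between the cultures of the 3 slides stays open.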
